A study of Mus musculus with 12 samples.

How the data were processed

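The series holds poly(A) RNA libraries from mouse E14 embryonic stem cells of the 129/Ola background, 2 for each of 6 groups. The groups are WT, a Dicer knockout (KO), and 4 Dicer-complemented lines named SOM, 41584, 41585 and 41589. According to the descriptions, 41584 resembles WT, 41585 processes neither miRNAs nor siRNAs, and 41589 lacks siRNA processing. What the names SOM, 41584, 41585 and 41589 stand for is not given in the sources used here, and neither is the part of Dicer1 that was deleted or the sequence put back. Cells grew in serum and LIF on gelatin, with puromycin in the medium. Libraries were made with TruSeq reagents, reverse-stranded, and read on a HiSeq2000. Reads were aligned by the submitters with STAR 2.4.2a to mm10 (GRCm38). The program that counted reads and the annotation release it used are not given in the sources used here.

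The values deposited by the authors are raw counts, 1 whole number per gene and library, for 47643 Ensembl genes. Each of the 12 columns was mapped to its library by the sample descriptions. GENCODE M21, on the same genome build, gave a symbol and a position to 47224 genes and left 419 without one. It also gave a 3' UTR to 20797 genes. Coordinates are 1-based and refer to GRCm38.

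Differences between groups were tested with edgeR 4.0.16 (quasi-likelihood, robust, TMM scaling, 1 mean per group, all 12 libraries in the fit), after removing genes of low count with filterByExpr. This left 14629 genes, a common biological coefficient of variation of 0.278 and 6 residual degrees of freedom. Genes were called at a Benjamini-Hochberg adjusted p under 0.05 within each comparison. A second fit used DESeq2 1.42.0. Folds are log2 values ± standard error of the fit. Expression is in CPM, the reads of a gene over the TMM-scaled library total, as mean ± standard deviation over the 2 libraries of a group, so n = 2 on each side of every comparison. Replicate numbers are those of the sample descriptions, which do not say what libraries of the same number share.

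Where a group held no count for a gene, the fold is given as a lower bound against 3 counts over the group. Where it held 1 to 3 counts, the ratio is given with its 95% interval from counting error. Those bounds and intervals cover counting error only.

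A set of 26 gene lists was fixed before the data were examined, and at least 5 tested members were needed for a test. Each list was tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset correlation between genes of 0.01, adjusted over the lists of a comparison. The same test with a correlation estimated from the data served as an alternative. So did fry, which asks whether a list moves against no change and does not compare it with other genes. For every list the number of members called over all genes is given together with the number called when p was adjusted over the list alone. List medians with members of 3 or fewer counts set to their bound were computed as well. They equalled the plain medians in every list called by camera except the interferon list in 41589 against 41584, where both are given.

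Target sites were searched in the 3' UTRs of 12890 tested genes with a UTR of at least 50 nucleotides. The log2 fold change was regressed on the presence of each 7-mer with UTR length and GC content as covariates, and the coefficient of a site was ranked among those of all 7-mers. The p-value is the share of 7-mers with a coefficient at least as far from 0, adjusted over 10 sites, of which 3 belong to miRNAs of other tissues. Ranking by coefficient over standard error was added after the data were seen. Genes are not independent, so the errors of these coefficients are too small by an unknown amount.

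The comparisons, filter, test, lists, sites and the rule for naming genes were chosen before the data were examined. That rule takes Dicer1 and the small RNA machinery in every comparison. It adds the genes with the largest folds among those called with a mean of at least 5 CPM and an ordinary symbol, 8 higher and 8 lower for KO against WT and 4 and 4 elsewhere. Of each list it takes up to 4 tested members with the smallest adjusted p, plus any needed to state what the list did. Removing the GC and length trend of each library, leaving out chromosomes 15 and Y with the Meg3 region, and the second ranking of sites were chosen after seeing the data.

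The p-values measure only the spread between these libraries, since the descriptions do not say whether the 2 libraries of a group came from separate cultures. When 1 library was left out, the lone library of its group was assumed to vary like the other groups. In simulated counts with the observed spread and 50 changed genes per fold, edgeR recovered 6% of the 2-fold changes, 64% of the 4-fold, 82% of the 8-fold and 100% of the 16-fold ones, with 10 calls among unchanged genes. With more genes changed it recovered 32.7%, 80%, 92.5% and 96.8%, with 73 such calls. A site effect of 0.2 planted over shuffled genes came back as 0.201 ± 0.032. Tables were handled with R 4.3.3, Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures were drawn with matplotlib 3.10.9.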

Results

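Poly(A) libraries from mouse embryonic stem cells, 12 in all, were compared to ask what the loss of Dicer does to the transcriptome, and which of those changes are absent from lines in which Dicer was put back. The libraries held between 5348401 and 10428509 counted reads. Mitochondrially encoded genes took 3.17 to 5.18% of the reads and the 10 most abundant genes 6.3 to 8.31%. TMM factors lay between 0.9039 and 1.079.

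The first principal component of log2 CPM carried 47% of the variance and placed the KO libraries (69.9 and 56.4) and the 41585 libraries (82.3 and 75.1) on one side. The WT, SOM, 41584 and 41589 libraries lay on the other, from −5.2 to −71.4. The second component, with 19.5%, put both SOM libraries and replicate 2 of 41584 and 41589 at −39.6 to −51.1, and the other libraries at −3.6 to 53.8. The 2 libraries of a group correlated at 0.975 in WT, 0.983 in KO, 0.967 in SOM, 0.935 in 41584, 0.973 in 41585 and 0.948 in 41589. Across groups, replicate 2 of WT correlated at 0.98 with replicate 1 of 41584 and at 0.98 with replicate 1 of 41589, above the values within those lines.

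Dicer1 mRNA fell from 206 ± 11.4 CPM in WT to 36.3 ± 11 CPM in KO (log2 fold −2.50 ± 0.36, n = 2, adjusted p = 0.0015). The gene lies at chromosome 12: 104687742–104751952 and encodes the RNase that cuts miRNA and siRNA precursors. SOM libraries held 105 and 215 CPM, and their Dicer1 level was not called different from WT (−0.36 ± 0.34, adjusted p = 0.535). Against KO, Dicer1 was higher in SOM (2.14 ± 0.35, adjusted p = 0.00515), a call that was lost without replicate 1 of KO (adjusted p = 0.081). In 41585, Dicer1 fell by a log2 fold of 2.59 ± 0.36 against WT (adjusted p = 0.00116), with 29.1 and 39.2 CPM. The reads assigned to Dicer1 were also few in 41584 (42.3 and 55 CPM) and 41589 (40.2 and 27.8 CPM). Over all genes neither of these last 2 differences from WT was called (41584: −2.08 ± 0.35, adjusted p = 0.347; 41589: −2.60 ± 0.36, adjusted p = 0.097). Within the small RNA machinery list alone, adjusted p was 0.000994 for 41584 and 0.000126 for 41589. Leaving out replicate 1 of 41589 made its Dicer1 difference a call over all genes (−2.88, adjusted p = 0.0177). Which part of the Dicer1 sequence in these lines the counts can see is not given, so these levels do not measure the Dicer protein that was put back.

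**Figure D1:**
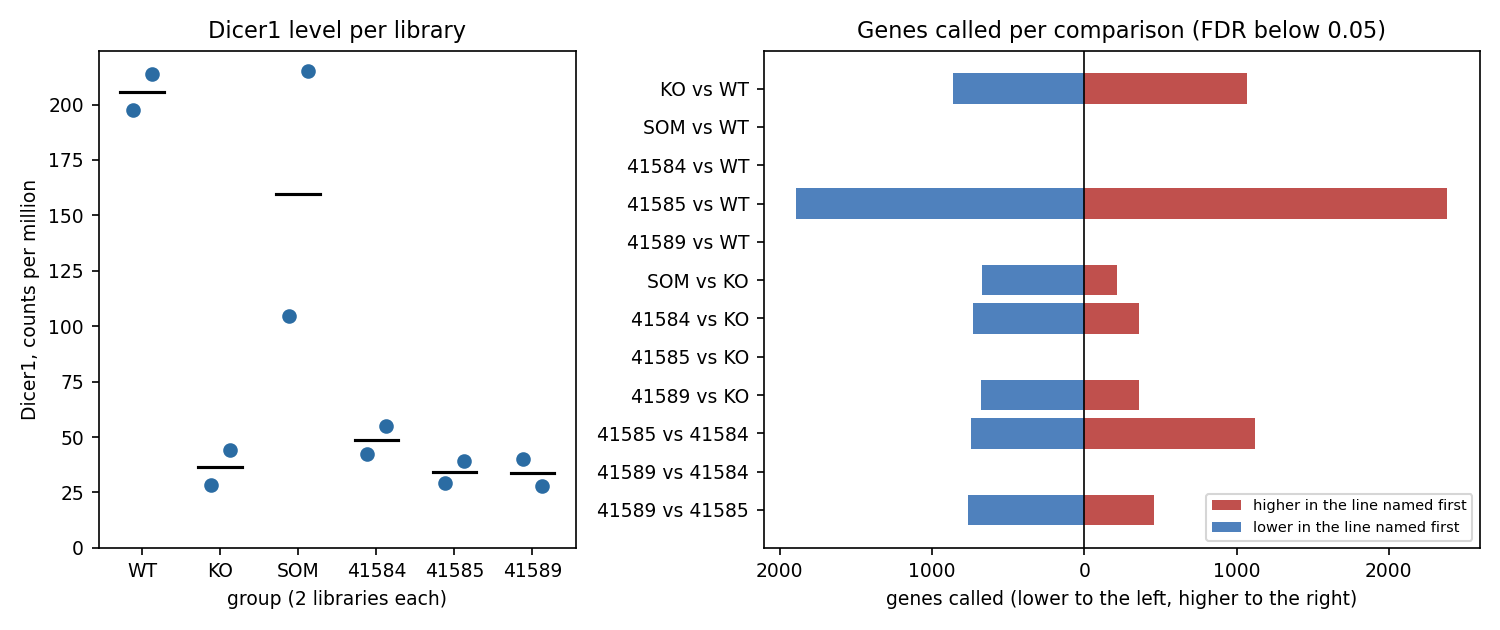
Dicer1 expression in each library in CPM, and the number of genes called higher and lower in each of the 12 comparisons.

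Between KO and WT, 1066 genes were called higher in KO and 863 lower, of the 14629 tested (n = 2 per group). With only these 2 groups in the fit the calls were 4892 (2529 higher and 2363 lower), and with no filter on low counts 2950. C1qtnf9, a secreted protein of the adiponectin family, rose from 0.132 ± 0.032 to 25.2 ± 6.93 CPM, a ratio of 55.3 to 1670 by counting error. Gbp2, an interferon-induced GTPase (chromosome 3: 142620602–142638008), reached 14.1 ± 3.46 CPM in KO with a ratio of 30.8 to 936. The glycosyltransferase gene Gcnt3 (ratio 40.5 to 1230), the ubiquitin ligase gene Sh3rf2 (31.2 to 949) and the membrane protein gene Sypl2 (28.6 to 870) rose as well. Krtdap, of keratinocytes, had a ratio of 45.2 to 648 and was not called without replicate 1 of WT (adjusted p = 0.0633). The immunity GTPase gene Irgm1, with a ratio of 42.4 to 1280, was not called without replicate 1 of WT (0.105), replicate 2 of WT (0.0796) or replicate 1 of KO (0.0645).

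Among the lowered genes, Matn3, which encodes a cartilage matrix protein (chromosome 12: 8947929–8972028), fell from 16.1 ± 1.73 CPM in WT to 0.138 ± 0.0226 in KO, a ratio of 32 to 969. Acan, the cartilage proteoglycan aggrecan (chromosome 7: 79053483–79115099), fell from 15.7 ± 0.0931 to 0.642 ± 0.472 CPM (−4.52 ± 0.78). Kdelr3, an endoplasmic reticulum retrieval receptor on chromosome 15, fell by 5.12 ± 0.89, a call lost without replicate 1 of KO (adjusted p = 0.0703). Leaving out that library also ended the calls of the X-linked genes Efhc2 (−6.07 ± 1.03, adjusted p = 0.052 without it) and Usp26 (−4.52 ± 0.75, 0.0533). The sulfotransferase gene Chst11 (−4.85 ± 1.10) gave 0.0882, 0.154 and 0.081 without replicate 1 of WT, replicate 1 of KO and replicate 2 of KO. The chromatin reader gene Trim66 (−4.72 ± 0.95) gave 0.0685, 0.11 and 0.0652 without the same libraries. Zfy1, on the Y chromosome (−4.81 ± 1.26), lost its call without each library in turn, with 0.154 and 0.052 without replicates 1 and 2 of WT and 0.0663 and 0.148 without replicates 1 and 2 of KO. It measured 49.5 and 20.6 CPM in WT and 2.32 in KO replicate 1, while KO replicate 2 held 0 counts of it and of the other Y-linked genes examined. Zfy1 was also low in SOM (1.37 and 0.376 CPM). Efhc2, at 216 and 40 CPM in WT, was low in SOM (1.89 and 1.69), 41584 (5.5 and 5.13) and 41589 (6.42 and 0.548). Kdelr3 was higher in SOM (33.4 and 24.4 CPM) than in KO (1.1 and 3.69). A difference between KO and WT therefore need not come from the loss of Dicer.

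Pluripotency genes moved in different directions. Klf4, a reprogramming factor, fell by 2.56 ± 0.27, and the let-7 antagonist Lin28a fell by 2.96 ± 0.37, whereas the related factor Klf2 rose by 1.53 ± 0.24. The Hippo kinase gene Lats2 rose by 4.21 ± 0.63, the chromatin protein gene Hmga2 by 2.44 ± 0.34 and the matrix gene Sparc by 2.07 ± 0.23. Krt19, an epithelial keratin, rose by 3.32 ± 0.48, the immediate early gene Egr1 by 2.25 ± 0.35, and the synaptonemal complex gene Sycp3 fell by 2.80 ± 0.40. Of the 86 named genes called in KO against WT, 20 were called whichever library was left out, among them Klf4, Lin28a, Klf2, Lats2, Hmga2, Sparc, Krt19, Egr1 and Sycp3. The total of 1929 called genes was 244 without replicate 1 of WT, 606 without replicate 2 of WT, 237 without replicate 1 of KO and 548 without replicate 2 of KO. DESeq2 called 2468.

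Interferon-stimulated and double-stranded RNA sensing genes formed the list with the smallest p in KO against WT. Of its 26 tested members 18 rose and 0 fell (19 and 1 adjusted over the list alone), with a median of 1.92 and adjusted p = 4.79e-09, or adjusted p = 0.383 with an estimated correlation. The oligoadenylate synthetase-like gene Oasl2 rose by 6.35 ± 0.87 and the transcription factor gene Irf1 by 2.44 ± 0.37. Zbp1, a nucleic acid sensor, rose by 5.76 ± 0.96 and was not called without replicate 1 of WT (adjusted p = 0.059). By fry, which sets a list against no change and not against other genes, the interferon list had an adjusted p of 0.00351.

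Reported targets of the embryonic miRNAs with the AAGUGC seed rose as a list (20 tested, 6 higher and 0 lower, 9 and 0 over the list alone, median 0.75, adjusted p = 0.000301). That list had adjusted p = 0.531 with an estimated correlation and 0.0194 by fry, which does not compare it with other genes. Besides Lats2, it includes the Nodal inhibitor Lefty1 (2.91 ± 0.49), whose call was lost without replicate 1 of WT (adjusted p = 0.0606), and Irf2 (4.81 ± 0.85), lost without replicate 1 of KO (0.0527). Nodal, TGF-beta and BMP signalling genes, which share Lefty1, Lefty2 and Tgfbr2 with it, rose too (19 tested, 5 and 0, 5 and 0 over the list alone, median 0.44, adjusted p = 0.0154). Their adjusted p = 0.383 with an estimated correlation. In that list the inhibitor of differentiation Id3 rose by 2.85 ± 0.70, with adjusted p of 0.169 and 0.165 without replicate 1 of WT and replicate 1 of KO.

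Epithelial adhesion genes rose (19 tested, 7 and 0, 11 and 0 over the list alone, median 1.41, adjusted p = 0.000301), with adjusted p = 0.531 with an estimated correlation. Krt8, a simple-epithelium keratin on chromosome 15, rose by 4.41 ± 0.82 but was not called without replicate 1 of WT (0.0848). Immediate early stress genes rose (16 tested, 6 and 0, 11 and 0 over the list alone, median 1.32, adjusted p = 0.00154), with adjusted p = 0.531 with an estimated correlation. The zinc finger gene Klf6 rose by 1.40 ± 0.26 and gave 0.0552 and 0.0556 without replicate 1 and replicate 2 of WT. G1/S cell cycle regulators rose (22 tested, 4 and 1, 6 and 1 over the list alone, median 0.34, adjusted p = 0.0402), with adjusted p = 0.531 with an estimated correlation. With the GC and length trend removed, an alternative added after the data were seen, the G1/S list had adjusted p = 0.116. Cyclin D1 (Ccnd1) rose by 2.56 ± 0.54 and gave 0.126 without replicate 1 of WT and 0.0611 without replicate 1 of KO.

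Germline genes that are silenced by DNA methylation fell (21 tested, 1 higher and 6 lower, 2 and 11 over the list alone, median −1.82, adjusted p = 0.000301), with adjusted p = 0.575 with an estimated correlation. Dazl, a germ cell RNA-binding protein gene of that list, was lower in KO and gave adjusted p of 0.0985, 0.0873 and 0.0718 without replicate 1 of WT, replicate 1 of KO and replicate 2 of KO. Hox genes fell (7 tested, 0 and 1, 0 and 4 over the list alone, median −2.14, adjusted p = 0.012), with adjusted p = 0.531 with an estimated correlation. Their one call over all genes was Hoxc13 on chromosome 15 (−4.23 ± 0.86), which gave 0.0954 without replicate 1 of WT and 0.13 without replicate 1 of KO.

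The remaining lists were not called in KO against WT, though several held changed genes. Naive and core pluripotency genes (20 tested, 1 higher and 5 lower, 1 and 5 over the list alone) had a median of −0.37 and adjusted p = 0.298. Tcl1, a co-activator of Akt in that list, fell by 2.25 ± 0.37 and was not called without replicate 1 of KO (0.0594). Formative and primed epiblast genes (14 tested, 3 and 1, 5 and 1 over the list alone) had a median of 0.92 and adjusted p = 0.0593. The de novo methyltransferase gene Dnmt3b rose by 1.80 ± 0.43 there, with adjusted p of 0.18, 0.0518, 0.111 and 0.07 without replicates 1 and 2 of WT and replicates 1 and 2 of KO. The let-7 targets (20 tested, 3 and 2, 7 and 2 over the list alone), which hold Hmga2, Lin28a and Dicer1, had a median of 0.56 and adjusted p = 0.133. Trophectoderm genes (14 tested, 5 and 0, 6 and 1 over the list alone) gave a median of 0.74 and adjusted p = 0.133. Both Krt8 and Krt18 belong to the trophectoderm and the epithelial list.

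Targets of p53 (20 tested, 1 and 7, 3 and 8 over the list alone) had a median of −0.23 and adjusted p = 0.335. The p53 target Zmat3 fell by 1.36 ± 0.25 and gave 0.064, 0.0926 and 0.0522 without replicate 1 of WT, replicate 1 of KO and replicate 2 of KO. Apoptosis regulators (19 tested, 1 and 2, 1 and 2 over the list alone) had adjusted p = 0.801, imprinted genes (23 tested, 3 and 1, 3 and 1) 0.859, and primitive and extra-embryonic endoderm genes (15 tested, 2 and 1, 2 and 4) 0.76. Lamc1, a laminin gene of the endoderm list, rose by 1.98 ± 0.32 and was not called without replicate 1 of WT (0.0607). The imprinted receptor gene Igf2r fell by 1.69 ± 0.31, a call lost without replicate 2 of KO (0.07). Mesendoderm genes (7 tested, 2 and 2, 2 and 3 over the list alone) gave 0.92, neuroectoderm genes (9 tested, 3 and 1, 3 and 2) 0.575, and fibroblast markers (6 tested, 1 and 1, 1 and 2) 0.335.

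Mesenchymal transition genes (13 tested, 0 and 1, 0 and 1 over the list alone) had adjusted p = 0.76 and glycolysis genes (19 tested, 0 and 3, 0 and 3) 0.859. Zeb1, a repressor of epithelial genes in the mesenchymal list, fell by 1.70 ± 0.41 and gave 0.105, 0.0727 and 0.216 without replicate 1 of WT, replicate 2 of WT and replicate 1 of KO. The DNA methylation machinery (11 tested, 1 and 0, 1 and 0 over the list alone) had a median of −0.1 and a mean of 0.07, with the test pointing up at adjusted p = 0.859. Small RNA machinery genes (19 tested, 2 and 3, 2 and 3) gave 0.76, genes of the two-cell-like state (14 tested, 0 and 0) 0.801, ribosomal protein genes (24 tested, 0 and 0) 0.92 and mitochondrially encoded genes (13 tested, 0 and 0) 0.455. By edgeR no member of these last 3 lists was called, with or without adjustment over the list alone.

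**Figure D2:**
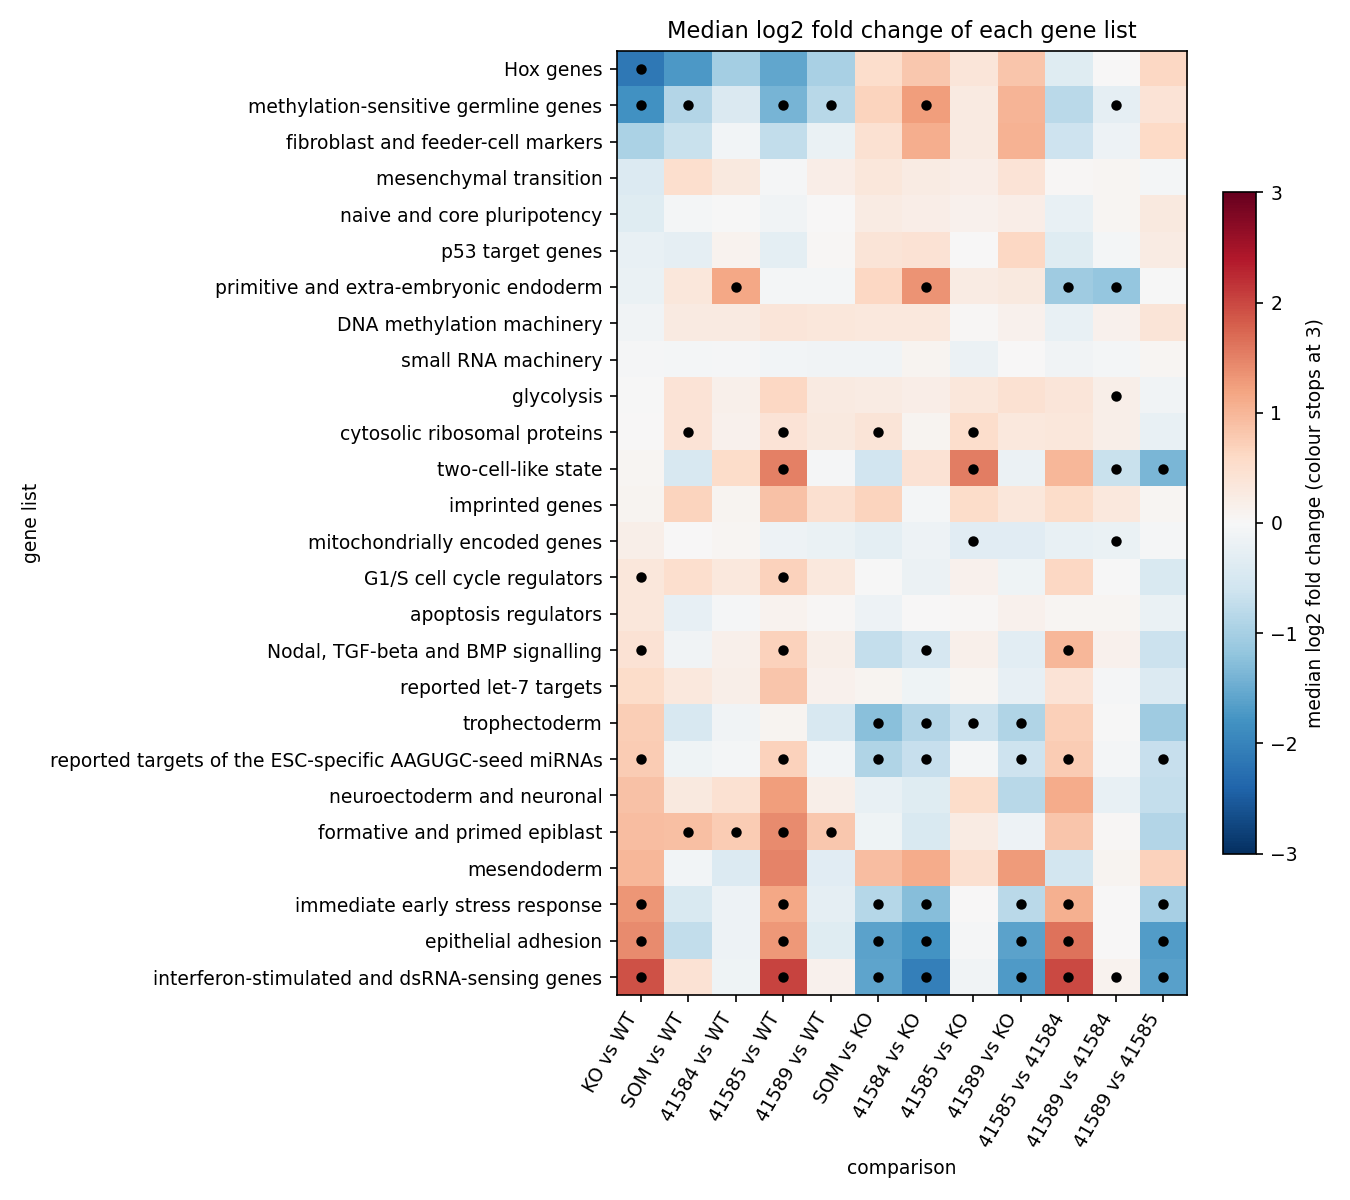
Median log2 fold change of each gene list in each comparison, with the lists called by camera marked.

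Within the small RNA machinery, the Argonaute gene Ago1 rose in KO (1.70 ± 0.34, adjusted p = 0.00868), a call lost without replicate 1 of WT (0.109) or replicate 1 of KO (0.0703). Tnrc6a, which encodes a silencing scaffold, rose by 1.06 ± 0.26 (adjusted p = 0.0198) but gave 0.128, 0.104, 0.116 and 0.103 without replicates 1 and 2 of WT and replicates 1 and 2 of KO. The terminal uridylyltransferase gene Tut4 fell by 0.99 ± 0.28 (adjusted p = 0.0379) and gave 0.252, 0.0683, 0.253 and 0.161 without those libraries. Ago4 fell by 2.57 ± 0.75 (adjusted p = 0.041), with 0.223, 0.0775, 0.224 and 0.203. Of the 5 machinery genes called in KO against WT, Dicer1 was the one called whichever library was left out.

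If embryonic miRNAs stop acting, mRNAs with sites for them should rise. The 7-mer AGCACTT, the site of the miR-290/miR-302 family, was present in the 3' UTR of 2286 of 12890 genes, and those genes lay 0.142 ± 0.031 higher in KO against WT than others of like UTR length and GC content. The planned ranking by coefficient placed it at 354 among all 7-mers (adjusted p = 0.252), so it was not called. Ranked by coefficient over standard error, a choice made after the data were seen, it came at rank 2 (adjusted p = 0.00122). The overlapping site GCACTTT of the miR-17 family, in 1887 genes, had 0.136 ± 0.033 and rank 4 by that second ranking (adjusted p = 0.00214, against 0.252 by coefficient). The let-7 site CTACCTC had −0.007 ± 0.037 (adjusted p = 0.93). Without UTR length and GC as covariates the AGCACTT coefficient was −0.008, and the medians with and without the site were −0.016 and 0.001. The 8-mer AGCACTTA, chosen before the data were examined and ranked among all 8-mers, had a coefficient of 0.331 and was called. A camera test of the genes with the AGCACTT site gave adjusted p = 0.961 in KO against WT, and adjusted p = 0.979 with an estimated correlation.

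The same site had coefficients of 0.166 ± 0.028 in 41585 against 41584 (adjusted p = 0.128 by coefficient, 0.000916 by the second ranking) and 0.162 ± 0.032 in 41585 against WT (0.205 and 0.00153). The direction of these 2 depended on the covariates, since without UTR length and GC they were −0.053 and −0.126. A camera test, which takes neither into account, put the genes with the site lower in both (adjusted p = 0.883 and 0.482). Against KO, the coefficient was −0.163 ± 0.027 in SOM (0.0692 and 0.00061), −0.145 ± 0.028 in 41584 (0.178 and 0.00122) and −0.139 ± 0.027 in 41589 (0.151 and 0.00122). In 41589 against 41585 the coefficient was −0.16 ± 0.027 (0.118 and 0.000916). It was −0.003 ± 0.014 in 41584 against WT, −0.021 ± 0.022 in SOM against WT, 0.002 ± 0.017 in 41589 against WT, 0.006 ± 0.01 in 41589 against 41584 and 0.021 ± 0.014 in 41585 against KO. Without the covariates the coefficients against KO were −0.171 in SOM, −0.065 in 41584, −0.127 in 41589 and −0.118 in 41585, and that of 41589 against 41585 was only −0.009. Those against WT became −0.179 in SOM, −0.073 in 41584 and −0.135 in 41589. By camera the genes with the site were called lower in SOM against WT (adjusted p = 0.0135), 41589 against WT (0.0489) and SOM against KO (0.0473). With an estimated correlation these 3 had adjusted p = 0.275, 0.441 and 0.666. Those camera calls were not particular to AGCACTT. The miR-26 site TACTTGA had smaller adjusted p by camera in SOM against WT (0.00353) and 41589 against WT (0.00439), but 0.357 in SOM against KO. GCACTTT had 0.0196 in SOM against KO. Sites of the miRNAs of other tissues were not called by camera in these comparisons. The miR-25/92 site GTGCAAT passed the second ranking in SOM against KO (0.00142), 41584 against KO (0.0212), 41589 against KO (0.00875), 41585 against 41584 (0.0114) and 41589 against 41585 (0.00651). The miR-19 site TTTGCAC passed it in SOM against KO (0.00427). A control site, GTGCCTT of the neuronal miR-124, also passed it in 41585 against 41584 (0.0461). Words outside the tested sites reached high coefficients over standard error as well. In 41585 against WT, CTTTTTT had 5.27, above the 5.09 of AGCACTT. In 41585 against KO, where AGCACTT did not pass, CCAGGCC had 5.53. In the other comparisons where AGCACTT passed, no word without GCACTT had a larger value in either direction. A high place in that ranking is therefore not particular to the tested sites.

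**Figure D3:**
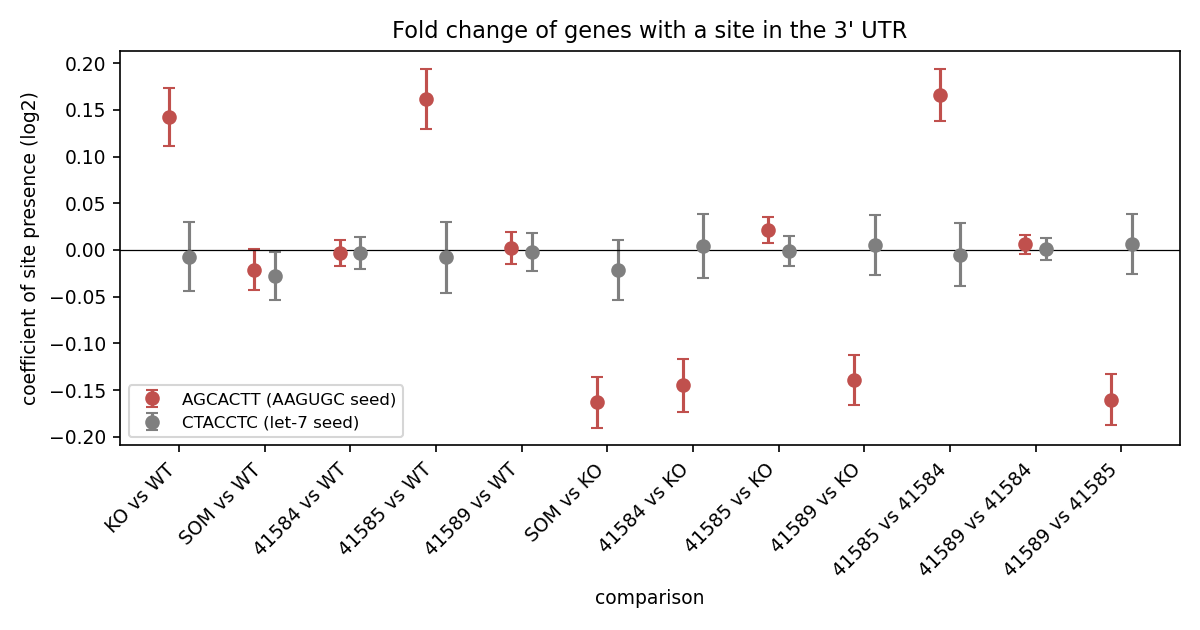
Regression coefficient of the miRNA sites AGCACTT (AAGUGC seed) and CTACCTC (let-7) in each comparison, with standard errors.

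Line 41585, described as lacking both miRNA and siRNA processing, was set against KO to ask whether it matches the knockout. No gene was called by edgeR (995 at an unadjusted p under 0.05, against 731 expected by chance), and DESeq2 called 1. With only the libraries of these 2 groups in the fit, however, 545 genes were called (481 higher and 64 lower), and with no filter on low counts 119. Dicer1 was at the KO level (−0.08 ± 0.35, adjusted p = 0.941). For 4949 genes (33.8%) the 95% interval of the fold lay within 2-fold. Leaving out replicate 1 of KO gave 4 calls and leaving out replicate 1 of 41585 gave 1. By camera, genes of the two-cell-like state were higher (median 1.53, adjusted p = 6.81e-05), with adjusted p = 0.929 with an estimated correlation. The embryonic genome activation gene Zscan4c measured 44.5 CPM against 14.9 (1.57 ± 0.80), and Usp17lc 1.57 ± 0.73, neither called. Ribosomal protein genes were higher (median 0.53, adjusted p = 0.000135), trophectoderm genes lower (−0.65, 0.0139) and mitochondrially encoded genes lower (−0.34, 0.0139). These 3 lists had adjusted p = 0.929 with an estimated correlation, and the mitochondrial call was lost when the GC and length trend was removed (0.744), a choice made after the data were seen. In these 4 lists 0 members were called by edgeR over all genes and 0 over the list alone.

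Against the line described as like WT, 41585 showed 1119 genes higher and 742 lower than 41584 (n = 2 per group). With only these 2 groups in the fit 403 were called (311 higher and 92 lower), and with no filter on low counts 3073. Oasl2 was at least 81.2-fold higher (279 and 0 counts), the guanylate-binding protein gene Gbp2b at least 66.7-fold and renin (Ren1) at least 64.6-fold. Aox3, an aldehyde oxidase gene, had a ratio of 42.3 to 9420. Krt19 rose by 4.02 ± 0.48, Lefty1 by 3.26 ± 0.49, Hmga2 by 2.55 ± 0.34, Irf1 by 2.76 ± 0.38, Oas1a by 3.23 ± 0.49, Klf2 by 1.65 ± 0.24 and the phosphatase gene Dusp1 by 2.16 ± 0.31. Lin28a fell by 3.60 ± 0.37, Klf4 by 2.04 ± 0.26, Sycp3 by 2.57 ± 0.40 and the membrane protein gene Steap1 by 4.28 ± 0.57. On chromosome 15, Kdelr3 fell by 5.08 ± 0.90, and the endocytic adaptor gene Dab2 by 5.41 ± 0.95, the latter not called without replicate 1 of 41585 (0.0569). Spink1, a protease inhibitor gene with a ratio of 30.8 to 6920, was not called without replicate 2 of 41584 (0.306), replicate 1 of 41585 (0.15) or replicate 2 of 41585 (0.102). Of 74 named genes called here, 18 were called whichever library was left out. In the fit of these 2 groups alone 49 of 73 named calls were lost. The 1861 calls became 348 without replicate 1 of 41585 and 561 without replicate 2 of 41585.

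In this comparison the interferon list rose (14 higher and 0 lower, 17 and 1 over the list alone, median 1.98, adjusted p = 5.35e-08), with adjusted p = 0.47 with an estimated correlation. Epithelial genes rose (11 and 0, 13 and 1 over the list alone, median 1.64, adjusted p = 1.04e-05; adjusted p = 0.47 with an estimated correlation). The tight junction gene Cldn7 rose by 3.41 ± 0.66 and was not called without replicate 1 of 41585 (0.0589). Immediate early genes rose (4 and 0, 10 and 0 over the list alone, median 1.07, adjusted p = 0.00201), with adjusted p = 0.47 with an estimated correlation. AAGUGC targets rose (4 and 0, 9 and 0 over the list alone, median 0.75, adjusted p = 0.00401), with adjusted p = 0.538 with an estimated correlation. Nodal, TGF-beta and BMP genes rose (3 and 0, 6 and 1 over the list alone, median 0.99, adjusted p = 0.0372), with adjusted p = 0.47 with an estimated correlation. Primitive and extra-embryonic endoderm genes fell (1 and 6, 1 and 7 over the list alone, median −1.06, adjusted p = 0.0216), with adjusted p = 0.527 with an estimated correlation. Some members of this list, such as Cubn and Gata4, were uneven between the 2 libraries of 41584. The receptor gene Pdgfra fell by 3.16 ± 0.66, with 0.0968 and 0.0657 without replicate 1 and replicate 2 of 41585. Ago1 rose by 1.30 ± 0.33 and gave 0.103, 0.0629 and 0.16 without replicate 1 of 41584, replicate 1 of 41585 and replicate 2 of 41585.

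Measured against WT, 41585 had 2383 genes higher and 1891 lower (n = 2 per group), the most of the 12 comparisons. Matn3 was at least 86.4-fold lower (0 and 248 counts) and Kdelr3 fell by 5.46 ± 0.91. Aox3 had a ratio of 46.3 to 10300, Ren1 37.7 to 8420 and C1qtnf9 49.2 to 1480. Klf4 fell by 2.48 ± 0.27 and Lin28a by 3.04 ± 0.37, while Lats2 rose by 4.40 ± 0.63, Lefty1 by 3.55 ± 0.50, Irf2 by 4.76 ± 0.85, Zbp1 by 6.08 ± 0.96, Id3 by 4.22 ± 0.70 and Krt19 by 4.24 ± 0.49. The hypoxia-responsive genes Slc2a3 and Bnip3 fell by 1.81 ± 0.32 and 1.68 ± 0.35. The neuronal gene Lrrn2 (ratio 49.6 to 11000) was not called without replicate 1 of WT (0.0634). Gch1, a biopterin synthesis gene (−4.72 ± 1.14), gave 0.0834 without replicate 1 of WT and 0.0759 without replicate 2 of 41585, and Chst11 (−4.56 ± 1.06) gave 0.0746 without replicate 1 of WT and 0.076 without replicate 1 of 41585. Ago1 rose by 1.92 ± 0.34, with 0.0601 without replicate 1 of WT, and Tut4 fell by 1.22 ± 0.29, with 0.108 without replicate 1 of WT and 0.087 without replicate 1 of 41585. Of 98 named genes called, 27 were called whichever library was left out. Without replicate 1 of WT the 4274 calls became 419, without replicate 2 of WT 2711, without replicate 1 of 41585 1239 and without replicate 2 of 41585 1595.

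Line 41585 had 9 lists higher and 1 lower than WT, and the interferon list again had the smallest p (16 higher and 1 lower, 18 and 1 over the list alone, median 2.02, adjusted p = 6.9e-06; adjusted p = 0.556 with an estimated correlation). Epithelial genes (10 and 0, 12 and 1 over the list alone, adjusted p = 0.0114), AAGUGC targets (6 and 0, 6 and 0, 0.0158), immediate early genes (8 and 0, 9 and 0, 0.0158) and G1/S regulators (7 and 1, 9 and 1, 0.0299) rose. Those 4 lists had adjusted p = 0.7 with an estimated correlation. Nodal, TGF-beta and BMP genes rose (6 and 1, 6 and 1 over the list alone, adjusted p = 0.0318), with adjusted p = 0.556 with an estimated correlation. Genes of the two-cell-like state (3 and 0, 2 and 0 over the list alone, adjusted p = 0.0191), formative genes (7 and 1, 8 and 1, 0.0338) and ribosomal protein genes (9 and 0, 10 and 1, 0.0445) rose, and germline genes fell (2 and 8, 3 and 9, 0.0191). For these last 4 lists adjusted p = 0.829 with an estimated correlation. Removing the GC and length trend, a choice made after the data were seen, ended 5 of the 10 calls, with adjusted p = 0.0898 for the formative, G1/S and germline lists, 0.125 for the immediate early list and 0.22 for ribosomal protein genes.

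KO against WT and 41585 against 41584 share no library, so they are separate comparisons. Each sets a line described as lacking Dicer or its processing against WT or a line described as like it. Over the 14629 genes their folds correlated at 0.79 (rank correlation 0.78), with a standard deviation of 0.145 over choices of single libraries. Genes called in both numbered 665 higher and 403 lower, against 82 and 44 expected if the lists were independent, and 0 went in opposite directions. A test of the difference between the 2 effects called 0 genes by edgeR (419 at an unadjusted p under 0.05; DESeq2 was not run for it). The slope of the second effect on the first was 0.8. Without replicate 1 of 41584 the correlation was 0.48. Klf4, Lin28a, Klf2, Hmga2, Irf1, Sycp3 and Krt19 were called in each of the 2 comparisons and in every fit with a library left out.

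**Figure D4:**
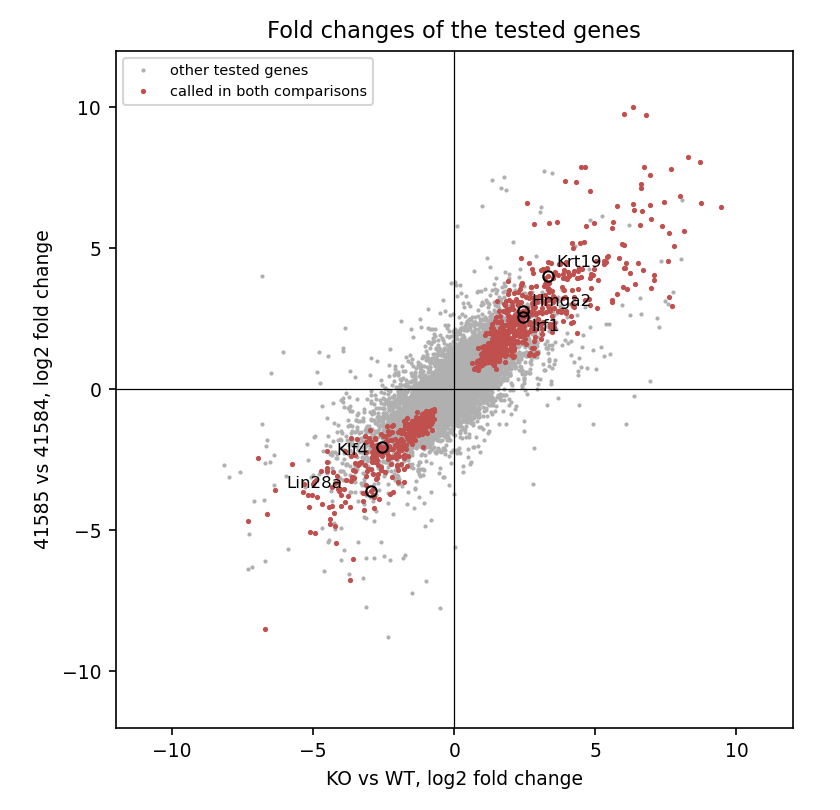
Log2 fold changes of KO against WT and of 41585 against 41584, comparisons that share no library, with genes called in both marked.

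Line 41584, described as like WT, was set against WT and then against KO. No gene was called against WT by edgeR (706 at an unadjusted p under 0.05, 731 expected by chance), and DESeq2 called 28. With no filter on low counts 132 were called. Leaving out replicate 1 of 41584 gave 106 calls, among them Lamc1 (adjusted p = 0.0439 without it). For 5437 genes (37.2%) the 95% interval lay within 2-fold. Endoderm genes were higher as a list (median 1.15, adjusted p = 4.12e-07; adjusted p = 0.23 with an estimated correlation), with 0 members called over all genes and 4 over the list alone. Those 4 were Lamc1 (1.82 ± 0.32), Sparc (0.99 ± 0.23), Cubn (2.32 ± 0.76) and Lama1 (1.30 ± 0.42). The vitamin B12 receptor gene Cubn measured 23.5 ± 21.8 CPM in 41584, uneven between its libraries. Formative genes were higher (median 0.77, adjusted p = 0.00455; adjusted p = 0.956 with an estimated correlation), with 1 member called over the list alone.

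Against KO, 41584 had 360 genes higher and 728 lower (n = 2 per group). The calls numbered 384 (71 higher and 313 lower) with only these 2 groups in the fit, 1858 with no filter on low counts and 1816 with the GC and length trend removed, a choice made after the data were seen. Oasl2 was at least 156-fold lower and Gbp2b at least 108-fold lower, with 0 counts of either in 41584. Krtdap had a ratio of 50.1 to 1510. Hmga2 fell by 2.58 ± 0.34, Irf1 by 2.53 ± 0.38, the apoptosis factor gene Xaf1 by 2.39 ± 0.35, Krt8 by 4.35 ± 0.82, Krt19 by 3.10 ± 0.47 and Klf2 by 1.43 ± 0.24. Lin28a rose by 3.52 ± 0.37, Klf4 by 2.12 ± 0.26, the X-linked gene Tro by 4.43 ± 0.42 and the glutathione peroxidase gene Gpx3 by 4.60 ± 0.52. Tgfbi, a matrix protein gene, rose by 4.70 ± 0.92 and gave 0.136 without replicate 1 of KO and 0.0563 without replicate 1 of 41584. Kdelr3 rose by 4.73 ± 0.88, with 0.105 without replicate 1 of KO. Tnrc6b, on chromosome 15, fell by 1.09 ± 0.28 and gave 0.24, 0.114 and 0.117 without replicate 1 of KO, replicate 2 of KO and replicate 2 of 41584. Dicer1 itself was not called (0.43 ± 0.34, adjusted p = 0.522). Of 59 named genes called, 18 were called whichever library was left out. In the fit of these 2 groups alone 29 of 59 named calls were lost. The 1088 calls became 203 without replicate 1 of KO and 374 without replicate 2 of KO.

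Interferon genes fell in 41584 against KO (0 higher and 16 lower, 0 and 18 over the list alone, median −2.05, adjusted p = 7.55e-12), with adjusted p = 0.234 with an estimated correlation. Epithelial genes (0 and 9, 0 and 13 over the list alone, adjusted p = 1.7e-07), AAGUGC targets (0 and 5, 0 and 7, 3.11e-05), immediate early genes (0 and 5, 0 and 8, 0.000228) and Nodal, TGF-beta and BMP genes (0 and 3, 0 and 4, 0.0303) fell. For each of these 4 adjusted p = 0.277 with an estimated correlation. Trophectoderm genes fell (0 and 5, 1 and 5 over the list alone, adjusted p = 0.0131; adjusted p = 0.545 with an estimated correlation). Endoderm genes rose (6 and 1, 6 and 1 over the list alone, median 1.35, adjusted p = 0.0023, or adjusted p = 0.277 with an estimated correlation), though Cubn and Gata4 of that list were uneven between the libraries of 41584. Lama1 rose by 2.12 ± 0.44, a call lost without replicate 1 of KO (0.164). Germline genes rose (2 and 1, 4 and 1 over the list alone, median 1.26, adjusted p = 0.0023; adjusted p = 0.693 with an estimated correlation). Sycp3 rose by 2.06 ± 0.39, with 0.0793 and 0.0764 without replicate 1 and replicate 2 of KO.

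SOM, whose Dicer1 level was not called different from WT, had no gene called against WT by edgeR (3175 at an unadjusted p under 0.05, 731 expected by chance), while DESeq2 called 681. With only these 2 groups in the fit 2035 genes were called, and with no filter on low counts 1345. Leaving out replicate 1 of SOM gave 1 call. The 95% interval lay within 2-fold for 3972 genes (27.2%). Lamc1 measured 379 ± 75 CPM in SOM and 98.8 ± 21.9 in WT (1.94 ± 0.32, adjusted p = 0.119, or 0.000706 over the endoderm list alone). Egr1 had 1.91 ± 0.35 (adjusted p = 0.121, or 0.00172 over the immediate early list alone) and the methyltransferase gene Dnmt3a 1.19 ± 0.25 (adjusted p = 0.135). As a list, formative genes were higher (median 0.9, 2 called over the list alone, adjusted p = 0.0016), ribosomal protein genes higher (median 0.41, 0 called over the list alone, 0.0122) and germline genes lower (median −0.89, 0 called over the list alone, 0.0201). Each of these 3 lists had adjusted p = 0.775 with an estimated correlation, and 0 members called over all genes. Removing the GC and length trend, chosen after the data were seen, ended the ribosomal call (0.267).

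Compared with KO, SOM had 216 genes higher and 673 lower (n = 2 per group). There were 2265 calls (746 higher and 1519 lower) with only these 2 groups in the fit, 1544 with no filter on low counts and 1559 with the GC and length trend removed, a choice made after the data were seen. Tro rose from 2.83 ± 2.1 to 54.5 ± 1.29 CPM (4.30 ± 0.42), Lin28a by 3.83 ± 0.38, the axon guidance gene Sema5b by 4.43 ± 0.59 and Klf4 by 1.72 ± 0.26. Gbp2b had a ratio of 45.3 to 10100 in favour of KO and the cytokine gene Osm of 26.4 to 801. Gbp2 fell by 4.46 ± 0.57, Oasl2 by 5.64 ± 0.85, Krt19 by 4.14 ± 0.52, the growth factor gene Fgf4 by 1.85 ± 0.27, Dusp1 by 2.21 ± 0.31 and Klf6 by 1.80 ± 0.26. The neuronal growth gene Gap43 (ratio 25.6 to 372) was not called without replicate 1 of KO (0.0635), nor Sh3rf2 (22.3 to 678) without replicate 1 of SOM (0.0537), nor Irf2 (18.5 to 565) without replicate 1 of SOM (0.0804). Tgfbi (4.61 ± 0.93) gave 0.16, 0.0518, 0.0515 and 0.0644 without replicates 1 and 2 of KO and replicates 1 and 2 of SOM. Tnrc6b fell by 1.36 ± 0.28, with 0.133, 0.0596, 0.185 and 0.0526 without those libraries. Of 53 named genes called, 12 were called whichever library was left out. The 889 calls became 139 without replicate 1 of KO, 307 without replicate 2 of KO, 107 without replicate 1 of SOM and 368 without replicate 2 of SOM.

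In SOM against KO, 5 lists fell and 1 rose, while 7 fell and 3 rose with the replicate number as a term of the fit. Interferon genes (0 higher and 12 lower, 0 and 16 over the list alone, median −1.59, adjusted p = 6.04e-10), epithelial genes (0 and 9, 0 and 11, 9.94e-09), AAGUGC targets (0 and 4, 0 and 14, 2.08e-07) and immediate early genes (0 and 7, 1 and 8, 0.0003) fell. For each of these adjusted p = 0.296 with an estimated correlation. Trophectoderm genes fell (0 and 5, 1 and 7 over the list alone, adjusted p = 0.00616; adjusted p = 0.485 with an estimated correlation). Krt8 fell by 5.16 ± 0.88, and gave 0.0724 and 0.0607 without replicate 1 and replicate 2 of SOM. Ribosomal protein genes rose as a list (0 and 0, 0 and 0 over the list alone, median 0.38, adjusted p = 0.00802; adjusted p = 0.825 with an estimated correlation), a call lost when the GC and length trend was removed (0.0687), a choice made after the data were seen. Lefty1 fell by 3.08 ± 0.51, a call lost without replicate 1 of SOM (0.0819).

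Line 41589, described as lacking siRNA processing, had no gene called against WT by edgeR (1719 at an unadjusted p under 0.05, 731 expected by chance), and DESeq2 called 75. With no filter on low counts 541 were called. Without replicate 1 of 41589, 647 genes were called. These included Lamc1 (2.20, adjusted p = 0.0177), Egr1 (2.04, 0.0189), Dnmt3a (1.45, 0.0223) and Dazl (−2.40, 0.0365). With all libraries Lamc1 had 1.80 ± 0.32 (adjusted p = 0.19), Dnmt3a 1.36 ± 0.25 (0.19) and Egr1 1.75 ± 0.35 (0.286). The 95% interval lay within 2-fold for 4846 genes (33.1%). Formative genes were higher as a list (median 0.81, 1 called over the list alone, adjusted p = 0.00183) and germline genes lower (median −0.83, 0 called over the list alone, 0.00105), each with adjusted p = 0.88 with an estimated correlation.

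Relative to KO, 41589 had 357 genes higher and 680 lower (n = 2 per group). With no filter on low counts 1768 were called, and 1805 with the GC and length trend removed, a choice made after the data were seen. Tro rose by 4.43 ± 0.42, Gpx3 by 4.49 ± 0.51, Lin28a by 3.47 ± 0.37 and Klf4 by 2.01 ± 0.26. Oasl2 fell by 6.69 ± 0.87, Krtdap by 6.62 ± 1.13, Gbp2 by 6.07 ± 0.61, Krt8 by 5.02 ± 0.84, Cldn7 by 4.12 ± 0.68, the receptor gene Tgfbr2 by 2.88 ± 0.50, Hmga2 by 2.70 ± 0.34, Xaf1 by 2.37 ± 0.35 and Klf6 by 1.64 ± 0.26. The ratio of KO to 41589 was 39.6 to 571 for Osm and 33.7 to 1030 for Irf2. Gap43 (ratio 18.7 to 270) and Tgfbi (4.94 ± 0.92) were not called without replicate 1 of KO (0.0793 and 0.118). Tnrc6a fell by 1.01 ± 0.26 and gave 0.18, 0.163, 0.0736 and 0.113 without replicates 1 and 2 of KO and replicates 1 and 2 of 41589. Dicer1 was not called (−0.09 ± 0.34, adjusted p = 0.916). Of 57 named genes called, 15 were called whichever library was left out. The 1037 calls became 186 without replicate 1 of KO, 376 without replicate 2 of KO and 650 without replicate 1 of 41589.

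Interferon genes fell in this comparison too (0 higher and 11 lower, 0 and 18 over the list alone, median −1.7, adjusted p = 3.68e-11; adjusted p = 0.267 with an estimated correlation). Epithelial genes (0 and 7, 0 and 11 over the list alone, adjusted p = 4.24e-08), AAGUGC targets (0 and 5, 0 and 8, 4.61e-06) and immediate early genes (0 and 5, 0 and 7, 0.00016) fell, each with adjusted p = 0.322 with an estimated correlation. Trophectoderm genes fell (0 and 5, 1 and 6 over the list alone, adjusted p = 0.0051; adjusted p = 0.47 with an estimated correlation).

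Set against 41585, which lacks both kinds of processing by its description, 41589 had 455 genes higher and 764 lower (n = 2 per group). With only these 2 groups in the fit 563 were called (125 higher and 438 lower), and with no filter on low counts 2271. Gap43 was at least 61.4-fold higher (229 and 0 counts), Steap1 rose by 4.40 ± 0.57, Lin28a by 3.55 ± 0.37 and Klf4 by 1.93 ± 0.26. Sh3rf2 fell by 6.39 ± 0.81. Gbp2 fell by 5.97 ± 0.61, Oasl2 by 5.74 ± 0.86, Cldn7 by 4.07 ± 0.68, Krt19 by 3.73 ± 0.46, Hmga2 by 2.66 ± 0.34, Irf1 by 2.25 ± 0.36, Dusp1 by 1.88 ± 0.30, Klf2 by 1.64 ± 0.24 and Sparc by 1.44 ± 0.23. The mesoderm gene Evx1 was at least 52.7-fold lower, and the ratio was 40.2 to 578 for Osm and 30.9 to 942 for Irf2. Eno2 (4.28 ± 0.83) was not called without replicate 2 of 41585 (0.0753). Kdelr3 (4.60 ± 0.89) gave 0.06, 0.0751 and 0.0613 without replicate 1 of 41585, replicate 2 of 41585 and replicate 1 of 41589. Ago1 fell by 1.21 ± 0.33 and gave 0.0838, 0.249 and 0.23 without those libraries. Of 59 named genes called, 17 were called whichever library was left out. The 1219 calls became 306 without replicate 1 of 41585, 409 without replicate 2 of 41585, 321 without replicate 1 of 41589 and 2435 without replicate 2 of 41589.

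The interferon list fell between these lines (0 higher and 12 lower, 0 and 17 over the list alone, median −1.62, adjusted p = 4.78e-08), as did epithelial genes (0 and 9, 1 and 14, 1.48e-06) and immediate early genes (0 and 4, 0 and 5, 0.000507). For these 3 adjusted p = 0.316 with an estimated correlation. AAGUGC targets fell (0 and 5, 0 and 7 over the list alone, adjusted p = 0.000402; adjusted p = 0.423 with an estimated correlation). Genes of the two-cell-like state fell (0 and 2, 0 and 6 over the list alone, median −1.37, adjusted p = 5.66e-05; adjusted p = 0.658 with an estimated correlation). Tdpoz3, a gene of that state, fell by 3.67 ± 0.73 and gave 0.0515 without replicate 1 of 41585 and 0.0631 without replicate 1 of 41589. Tdpoz4 fell by 3.68 ± 0.83, with 0.0721, 0.0619, 0.0586 and 0.0553 without replicates 1 and 2 of 41585 and replicates 1 and 2 of 41589.

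The comparison of 41589 with 41584 asks what the lack of siRNA processing adds. EdgeR called no gene (103 at an unadjusted p under 0.05, 731 expected by chance) and DESeq2 called 0, while 3 were called with no filter on low counts. Since 103 lies well below 731, the p-values here were larger than a calibrated test would give. The libraries of 41584 correlated at 0.935 and those of 41589 at 0.948, below the 0.977 between replicates 1 of the 2 lines. The absence of calls therefore does not show that the lines are alike. Leaving out replicate 2 of 41589 gave 1 call. Here 6577 genes (45%) had a 95% interval within 2-fold. Endoderm genes were lower as a list (median −1.17, adjusted p = 3.23e-11; adjusted p = 0.0787 with an estimated correlation), with 0 members called over all genes and 2 over the list alone. Those were Gata4, a transcription factor gene (−2.61 ± 0.79), and Cubn (−2.60 ± 0.76), each at 0.0423 over the list alone. Without replicate 1 of 41584 their folds were −0.47 and −1.06, and Gata4 measured 6.13 ± 6.69 CPM in 41584. Genes of the two-cell-like state (median −0.67, adjusted p = 2.09e-08) and germline genes (−0.26, 0.000184) were lower and interferon genes higher (0.1, or 0.04 with low members at their bound, 0.0388). Each of these 3 had adjusted p = 0.958 with an estimated correlation. Glycolysis genes were higher (median 0.17, adjusted p = 0.0248) and mitochondrially encoded genes lower (−0.2, 0.0388), each with adjusted p = 0.981 with an estimated correlation. With the GC and length trend removed, a choice made after the data were seen, the glycolysis call was lost (0.0654) and the mitochondrial list pointed the other way (0.718). In these 5 lists 0 members were called over all genes and 0 over the list alone.

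How much of the KO change was absent from each line was asked of the 1929 genes called in KO against WT. In 41584, 875 of them (45.4%) were called in the opposite direction against KO, in 41589 786 (40.7%), in SOM 583 (30.2%) and in 41585 0. The median gene had 0.8 of its KO change reversed in 41584, 0.73 in 41589, 0.61 in SOM and 0.02 in 41585, where 1650 genes were still called against WT. Because the KO libraries stand in both comparisons, part of these counts may come from the shared libraries. In 10 simulations per line with no reversal, the highest share was 0% and the median reversed part 0.08 to 0.09. These simulations drew each line from the KO mean, so few calls against KO could arise in them. They do not size the shared part for a line that differs from KO. Of the 1066 genes higher in KO, 563 (52.8%) went down in 41584, 505 (47.4%) in 41589 and 433 (40.6%) in SOM. If the calls of the 2 comparisons were independent, 53, 50 and 49 would do so. Of the 863 genes lower in KO, 312 (36.2%) went up in 41584, 281 (32.6%) in 41589 and 150 (17.4%) in SOM, against 21, 21 and 13 under independence. The shared KO libraries make the calls dependent, so these expected numbers do not size the overlap without a reversal. Lin28a and Klf4, low in KO, rose in the 3 lines, and Gbp2, Oasl2 and Hmga2, high in KO, fell in them. The Hmga2 call in SOM was lost without replicate 1 of KO (0.113), replicate 1 of SOM (0.0646) or replicate 2 of SOM (0.0809). With 1 library left out, the shares were taken over the genes called in KO against WT in that fit, not over the 1929. Leaving out replicate 1 of WT raised the shares in 41584, 41589 and SOM, over a much smaller set of genes. The share in 41584 was 20.9% without its replicate 1, that in 41589 16.4% and 25.8% without its replicates 1 and 2, and that in SOM 6.2% and 16.4%. For 41585 the share was 1.7% without replicate 1 of KO and 0.1% without replicate 1 of 41585.

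Within groups, the genes of chromosome 15 set replicates 1 and 2 apart in the complemented lines. The median difference over 371 genes, after removing the GC and length trend, was 0.33 in SOM, 0.47 in 41584, 0.52 in 41585 and 0.49 in 41589, with replicate 1 higher. It was 0.03 in KO and −0.07 in WT. Of the chromosome 15 genes 83.6% in SOM, 80.9% in 41584, 96% in 41585 and 84.1% in 41589 had the same sign, against 57.4% in KO and 57.1% in WT. A planted 1.5-fold gain (0.58) of the chromosome came back as 0.6. Kdelr3, Dab2, Krt8, Krt18, Hoxc13, Tnrc6b and Ddx17 lie on this chromosome. Over its 569 tested genes the median fold was −0.29 in SOM against WT, −0.15 in 41584 against WT, −0.15 in 41589 against WT, −0.05 in 41585 against WT and 0.03 in KO against WT. It was −0.25 in SOM against KO, −0.17 in 41584 against KO and 0.14 in 41585 against 41584.

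**Figure D5:**
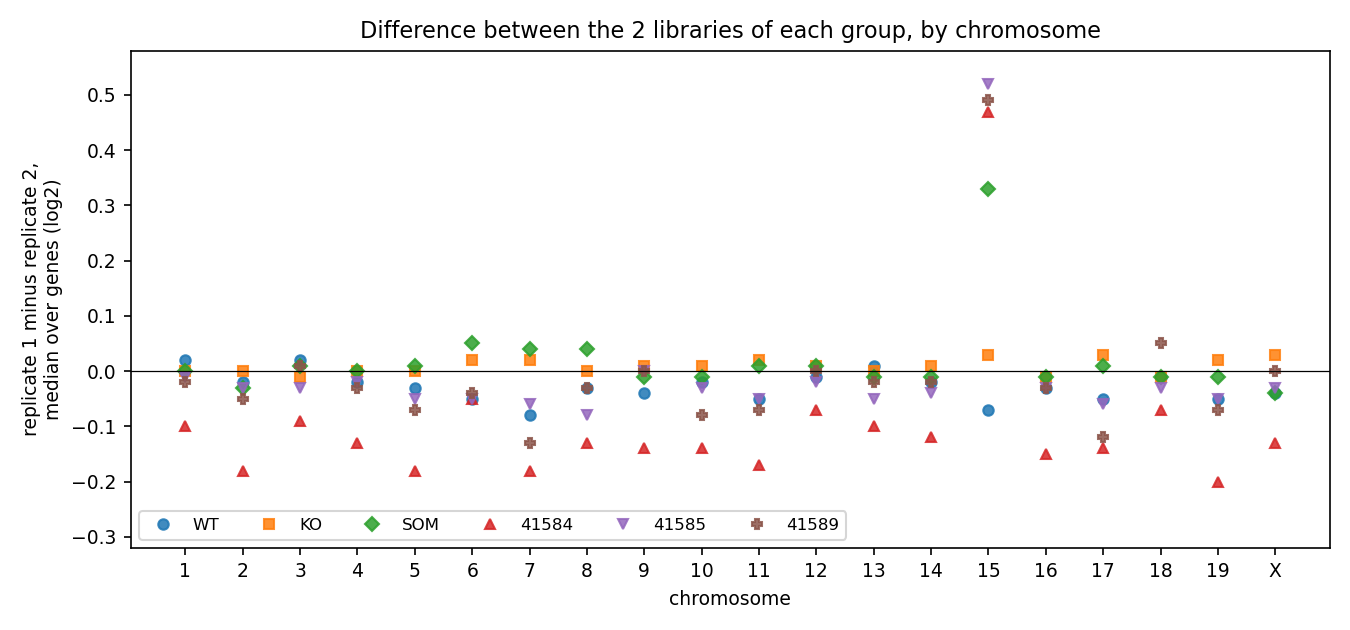
Median difference between replicate 1 and replicate 2 for the genes of each chromosome in each group, after removing the GC and length trend.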

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

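Each result was recomputed under the alternatives planned for it before the data were examined and those added for it after. For gene lists and miRNA sites these did not include leaving out libraries, another filter or DESeq2, so how far they depend on single libraries was not tested. Of the results that answer a comparison, 239 alternatives gave the same answer, 21 a stronger one, 90 moved it past the set limits and 12 reversed its sign. Of the 21 counted as stronger, 7 were the 6-mer and 7 the 8-mer site. Their p was not adjusted, while that of the 7-mer was, so those do not show a stronger result. Of the other results, mostly single named genes and lists, 5284 stayed the same, 1224 were weaker, 61 stronger, 3 moved and 12 reversed. The cause was not tested for any of the changes below. Scaling by DESeq2 size factors in edgeR, asking for at least 1 CPM in 2 libraries, asking for a fold of at least 2 as well, and leaving out chromosomes 15 and Y with the Meg3 region moved none of the results that answer a comparison (41, 17, 12 and 17 of them). Other pseudocounts were not run, since they were planned only for normalized values.

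Numbers of genes called depended most on the filter and on the libraries in the fit. With no filter on low counts, KO against WT gave 2950 genes, SOM against WT 1345, 41584 against WT 132 and 41589 against WT 541. Without it SOM against KO gave 1544, 41584 against KO 1858, 41585 against KO 119 and 41589 against KO 1768. It gave 3073 for 41585 against 41584, 3 for 41589 against 41584 and 2271 for 41589 against 41585. With only the libraries of the 2 groups compared, the counts were 4892 for KO against WT, 2035 for SOM against WT, 2265 for SOM against KO and 384 for 41584 against KO. In such fits 41585 against KO gave 545, 41585 against 41584 403 and 41589 against 41585 563. DESeq2 called 681 genes in SOM against WT, 28 in 41584 against WT, 75 in 41589 against WT and 1 in 41585 against KO. With the GC and length trend removed, an alternative added after the data were seen, the counts were 40 for SOM against WT, 16 for 41584 against WT and 15 for 41589 against WT. That setting gave 1559 for SOM against KO, 1816 for 41584 against KO and 1805 for 41589 against KO. For these counts the cause was not tested.

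Leaving out 1 library moved the number of calls in each of the 12 comparisons. KO against WT ranged from 237 (without KO replicate 1) to 606 (without WT replicate 2), with 244 without WT replicate 1 and 548 without KO replicate 2. 41585 against WT ranged from 419 (without WT replicate 1) to 2711 (without WT replicate 2), with 1239 and 1595 without replicates 1 and 2 of 41585. SOM against KO ranged from 107 (without SOM replicate 1) to 368 (without SOM replicate 2), with 139 and 307 without replicates 1 and 2 of KO. For 41584 against KO the range was 203 (without KO replicate 1) to 1332 (without 41584 replicate 2), with 374 without KO replicate 2. 41589 against KO ranged from 186 (without KO replicate 1) to 694 (without 41589 replicate 2), with 376 without KO replicate 2 and 650 without 41589 replicate 1. 41585 against 41584 ranged from 348 (without 41585 replicate 1) to 1820 (without 41584 replicate 1), with 561 without 41585 replicate 2. 41589 against 41585 ranged from 306 (without 41585 replicate 1) to 2435 (without 41589 replicate 2), with 409 without 41585 replicate 2 and 321 without 41589 replicate 1. SOM against WT had 1 without SOM replicate 1, 41584 against WT 106 without 41584 replicate 1, 41589 against WT 647 without 41589 replicate 1, and 41589 against 41584 1 without 41589 replicate 2. 41585 against KO had 4 without KO replicate 1 and 1 without 41585 replicate 1. Again the cause was not tested.

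Calls of named genes depended on the libraries in the fit as well. With only the 2 groups compared, 49 of 73 were lost in 41585 against 41584, 29 of 59 in 41584 against KO, 17 of 59 in 41589 against 41585, 9 of 57 in 41589 against KO, 1 of 84 in KO against WT and 1 of 96 in 41585 against WT. Removing the GC and length trend lost 14 of 98 in 41585 against WT, 13 of 74 in 41585 against 41584, 6 of 59 in 41589 against 41585, 3 of 59 in 41584 against KO and 2 of 86 in KO against WT. For the named genes the cause was not tested.

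The correlation between KO against WT and 41585 against 41584 ranged from 0.48 (without 41584 replicate 1) to 0.81 (without 41584 replicate 2). The shares given next were taken over the genes called in KO against WT in each fit, so they cover different sets of genes. The share of KO changes reversed ranged from 6.2% (without SOM replicate 1) to 79.9% (without WT replicate 1) in SOM, with 16.4% without SOM replicate 2. In 41584 it ranged from 20.9% (without 41584 replicate 1) to 94.3% (without WT replicate 1). In 41589 it ranged from 16.4% (without 41589 replicate 1) to 90.6% (without WT replicate 1), with 25.8% without 41589 replicate 2. In 41585 it was 1.7% without KO replicate 1 and 0.1% without 41585 replicate 1. Here too the cause was not tested.

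Of 65 list calls, 65 were lost with an estimated inter-gene correlation, which left 0 lists called in KO against WT, SOM against WT, 41584 against WT, 41585 against WT and 41589 against WT. The same setting left 0 in SOM against KO, 41584 against KO, 41585 against KO and 41589 against KO, and 0 in 41585 against 41584, 41589 against 41584 and 41589 against 41585. With fry 30 of the 65 were lost, and 0 lists were called in SOM against WT, 41584 against WT, 41589 against WT, 41585 against KO and 41589 against 41584. Fry does not compare a list with other genes. Removing the GC and length trend lost 10 of the 65 calls. These were G1/S regulators in KO against WT (adjusted p = 0.116), ribosomal protein genes in SOM against WT (0.267), SOM against KO (0.0687) and 41585 against WT (0.22), mitochondrially encoded genes in 41585 against KO (0.744) and glycolysis genes in 41589 against 41584 (0.0654). In 41585 against WT the formative, G1/S and germline lists (0.0898 each) and the immediate early list (0.125) were lost as well. The same removal gave 8 lists in 41589 against 41585 and reversed the mitochondrially encoded genes in 41589 against 41584 (adjusted p = 0.718). For the lists the cause was not tested.

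The site AGCACTT had coefficients of −0.008 in KO against WT, −0.126 in 41585 against WT, −0.135 in 41589 against WT, −0.118 in 41585 against KO, −0.053 in 41585 against 41584 and −0.062 in 41589 against 41584 when UTR length and GC were not covariates, each with reversed sign. The 6-mer GCACTT was tested as a single site without adjustment, and had the other sign in 41589 against WT (−0.008). It was counted as stronger in KO against WT (0.106), 41585 against WT (0.11), SOM against KO (−0.142) and 41584 against KO (−0.12). The same held for 41589 against KO (−0.113), 41585 against 41584 (0.124) and 41589 against 41585 (−0.117). The 8-mer AGCACTTA, also tested as a single site, had p of 0.0143 to 0.0371 without adjustment in those comparisons. The coefficients of the 8-mer were 0.331 in KO against WT, 0.326 in 41585 against WT and −0.388 in SOM against KO. In 41584 against KO the 8-mer had −0.399, in 41589 against KO −0.362, in 41585 against 41584 0.393 and in 41589 against 41585 −0.357. Its sign was the other one in 41589 against WT (−0.031) and 41585 against KO (−0.005). Ranked by coefficient over SE, added after the data were seen, the unchanged coefficients passed in KO against WT (0.142), 41585 against WT (0.162), SOM against KO (−0.163), 41584 against KO (−0.145), 41589 against KO (−0.139), 41585 against 41584 (0.166) and 41589 against 41585 (−0.16). Removing the GC and length trend reversed the sign in SOM against WT (0.003) and 41584 against WT (0.003). For the site the cause was not tested.

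Dicer1 folds near 0 changed sign in SOM against WT without SOM replicate 1 (0.07, with −0.97 the lowest value, without SOM replicate 2) and in 41585 against KO without KO replicate 2 (0.22), without 41585 replicate 1 (0.09) and with the GC and length trend removed (0.01), where leaving out KO replicate 1 gave −0.37. They did so in 41589 against KO without KO replicate 2 (0.22) and without 41589 replicate 2 (0.12), where leaving out 41589 replicate 1 gave −0.38. In 41589 against 41585 they did so with no filter on low counts (0.02), without 41585 replicate 2 (0.24) and without 41589 replicate 2 (0.24), where leaving out 41589 replicate 1 gave −0.29. Dab2 in 41589 against 41584 changed sign without 41584 replicate 1 (0.36) and was −2.63 without 41584 replicate 2. For these folds the cause was not tested.

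A replicate block, the replicate number as a term of the fit, was also run. Deviations of replicate 1 from the group mean correlated between −0.08 and 0.51 over the 15 pairs of groups, above 0.1 in 5 of them. Since most pairs lay near 0, the numbers were not taken to pair all libraries, although chromosome 15 was lower in replicate 2 of all 4 complemented lines. Among those lines the correlation was 0.25 for SOM and 41584, 0.24 for SOM and 41585, 0.33 for 41584 and 41585 and 0.18 for 41584 and 41589. It was 0.04 for SOM and 41589 and −0.02 for 41585 and 41589. The highest value, 0.51, was that of WT and 41589, which are compared directly. A factor shared by replicates of the same number in part of the groups, WT and 41589 included, is therefore not excluded. With the replicate block 3 genes were called in SOM against WT and 1 in 41589 against WT, and 4 lists were called in 41584 against WT and 10 in SOM against KO. The AGCACTT coefficient in 41584 against WT became 0, and Dicer1 in 41589 against 41585 became 0.04. Of the 65 list calls 3 were lost. With the block the cause was not tested.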

Other observations

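Some named genes changed in the same direction relative to KO in each of SOM, 41584 and 41589. All of these comparisons use the same KO libraries, so their folds are not independent. Tro, an X-linked gene of trophoblast adhesion, rose by 4.30 ± 0.42, 4.43 ± 0.42 and 4.43 ± 0.42 in the 3 lines, from 2.83 ± 2.1 CPM in KO, and was called whichever library was left out. Xaf1 fell by 2.39 ± 0.35 in 41584 and by 2.37 ± 0.35 in 41589. In SOM it fell by 1.91 ± 0.35, a call lost without KO replicate 1 (adjusted p = 0.0545) or SOM replicate 1 (0.0867). The insulin-like growth factor gene Igf2 had folds of −4.60 ± 0.91, −3.75 ± 0.86 and −4.76 ± 0.90 in SOM, 41584 and 41589, but its call was lost in 41584 without each of the 4 libraries in turn (0.0611 to 0.0985), in SOM without KO replicate 2 (0.0545), SOM replicate 1 (0.0819) or SOM replicate 2 (0.0969), and in 41589 without 41589 replicate 1 (0.0514).

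Genes of chromosome 15 were lower in replicate 2 than in replicate 1 of SOM, 41584, 41585 and 41589, and all tests of this pattern were chosen only after the result was seen. After removing the trend on GC content and length, the smallest median difference in the 4 lines was 0.33, in SOM. Other chromosomes lay between −0.2 and 0.05 in those 4 lines, so a GC or length bias is argued against. A few genes are argued against as well, because at least 80.9% of the genes were higher in replicate 1 in each line. A candidate explanation is a different number of copies of the whole chromosome in part of the cells, since the medians of its 6 bins of 10 Mb with at least 20 genes ran from 0.23 to 0.59 in these lines, though its 5 bins with fewer genes ran from 0.05 to 0.74.

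The folds of Tnrc6b, −1.36 ± 0.28 in SOM against KO and −1.09 ± 0.28 in 41584 against KO, include the chromosome's shift of −0.25 and −0.17. Genes of the Y chromosome, chosen after their values were seen, differed between the KO libraries. Ddx3y measured 219 CPM in replicate 1 and 0 counts in replicate 2, with Eif2s3y at 116, Uty at 53.4 and Uba1y at 28.8 CPM in replicate 1 and 0 in replicate 2. No explanation was tested for the Y chromosome.

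Meg3 and Rian were named after their values were seen, and of their tests the one on read depth was chosen only after the result was seen. Meg3, a maternally expressed noncoding RNA (chromosome 12: 109541001–109571726), was near absent in KO replicate 2 (1.08 CPM) and 41584 replicate 1 (1.53 CPM), against 70.5 to 202 CPM in the other libraries. Rian, its neighbour, measured 8.78 and 8.95 CPM there, against 198 to 657. Too few reads are argued against by the counts expected from the other library of each group, 878 and 1466 where 7 and 12 were seen. Gain of a paternal-like imprint on the maternal copy may be the source, but Dlk1 and Rtl1, which should then rise, held so few reads that their ratio in KO was 1.26 with an interval of 0.0161 to 99.1. A general loss of imprinting was expected to move many other imprinted genes over 4-fold between the 2 libraries, and fewer did than expected, 0 of 19 in KO and 3 of 19 in 41584. These last 2 explanations cannot be told apart, because Dlk1 and Rtl1 were near 0 in both libraries of each group and a second active copy of an imprinted gene could raise it by less than 4-fold.

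Loss of siRNA processing could release mRNAs that siRNAs are reported to target in oocytes, and the test of this was chosen before the result was seen. Over 6 such genes the median was 0.05 in 41589 against 41584, with a bootstrap interval of −0.09 to 0.23. By the limits set beforehand these mRNAs were thus not higher as a set in 41589 than in 41584. The interval resampled the genes and does not cover the spread between libraries. In 41585 against 41584 the median was 0.36 (−0.43 to 0.82). Whether siRNAs act on them in these cells was not shown, so the test cannot decide on a release of these mRNAs. Against WT their median was 0.37 (−0.09 to 0.51) in 41589, 0.17 (0.01 to 0.43) in 41584, 0.72 (−0.42 to 1.06) in 41585, 0.51 (−0.03 to 0.92) in SOM and 0.58 (−0.05 to 0.94) in KO.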
